A study of Brevundimonas diminuta and Stutzerimonas balearica and Brevundimonas diminuta
Stutzerimonas balearica with 27 samples.

How the data were processed

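RNA of 27 samples was sequenced after rRNA removal with a stranded mRNA library kit, per the labels. For each strain the authors deposited raw read counts per ORF and, beside them, RPKM values (counts scaled by coding length and library total), per the file headers. RPKM recomputed from the counts, the coding lengths and the column totals differed by at most a relative 5.0e-10 in the R79 table and 1.7e-09 in the R90 table. SAMtools is the only tool in the submitters' processing notes, without a version, and the aligner, genome build, annotation source and use of strand are not given in the sources used here. No pair of libraries was identical. Between replicate libraries the chi-square per degree of freedom of the counts was 1.51 to 97.9, where counting error alone gives about 1. The tables hold no columns for a strain's ORFs in libraries of the other strain alone, so reads counted to the wrong strain could not be measured. Products are those of the tables, in which 28.0% of R79 and 28.2% of R90 ORFs have no named product, and duplicated annotations and paralogs make single ORFs uncertain.

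Counts were tested with edgeR 4.0.16 (TMM factors, glmQLFit and glmQLFTest) in R 4.3.3, with a means model over the 6 groups of a strain, and Benjamini-Hochberg adjustment over all genes. Genes with an RPKM of at least 1 in at least 3 of 18 libraries were tested, which removed none of the 3198 and 4288 ORFs. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1, and standard errors were derived from the F statistic. Normalised RPKM means RPKM after TMM scaling. Gene lists, 21 in number, were matched to product names, and those with at least 5 members were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists and comparisons of a strain), and again with an estimated correlation. Groupings, comparisons, tests, lists, alternatives and the rule for naming genes were set before the data were examined, with limma on RPKM as the test unless counts were present. After product names but not values were seen, false matches were taken out of the lists and wider lists of ribosomal proteins and of amino acid biosynthesis by enzyme name were added. The rule named the 10 largest rises and 10 largest falls at days 4 and 7, and the 5 largest each way elsewhere, among called genes with non-overlapping groups, a mean of at least 10 in the higher group and a named product, and up to 4 members per list with the largest absolute change. For the interaction, non-overlap was judged on the differences between cultures. A group with 0 counts was given a floor of 3 counts over the group, and ratios with 1 to 3 counts carry a 95% counting interval.

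The alternatives were values as deposited (no library factor), quantile normalization, DESeq2 size factors, DESeq2 1.42.0, limma on log2(RPKM + 1) with added values of 0.1 and 10 in place of 1 and with a robust prior, a robust edgeR dispersion, no filter, a mean RPKM of at least 10, only the groups of the comparison, a replicate block and each library left out in turn. After the data were seen, the count filter of edgeR, fits without the ORFs above 0.5% of counts on average (12 in R79 and 13 in R90) and a fit without co-culture replicate 1 of day 7 were added. The count filter was looked at before the RPKM filter was kept. In tests on simulated data with 100 changed genes per fold, 4-fold changes were called in 65% to 95% and 2-fold changes in 14% to 30%, with 2 to 9 unchanged genes called. Other splits of the libraries were tested with the groups of a comparison alone. Shares and figures were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.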

Results

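RNA sequencing followed strains R79 (Brevundimonas diminuta) and R90 (Pseudomonas balearica, Stutzerimonas balearica in some labels), each grown alone or both mixed at 1:1, in a saline medium with 5 g/L sodium acetate and 16 g/L NaCl at 30 °C. Samples were taken at days 0, 4 and 7, and the 27 libraries form 9 groups of 3. One table counts 3198 R79 open reading frames (ORFs) and the other 4288 R90 ORFs, and the 9 mixed libraries appear in both, so each table holds 18 libraries. Libraries held 148700 to 1163077 R79 counts (median 361938.5) and 39421 to 8372766 R90 counts (median 1237967). The lowest, co-culture replicate 1 of day 7, reached 2841 R90 ORFs. Nothing in the labels says that the 3 samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Genes are named by product and ORF identifier, and the same identifiers stand for different genes in each strain. Values are normalised RPKM as mean ± SD with n = 3, log2 fold changes carry their standard error, and a gene is called at an adjusted p under 0.05 and a log2 fold change of at least 1 either way.

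How much of the RNA of the mixed cultures came from each strain was read from the shares of counts. R79 held 59.7% ± 2.16 of the ORF counts at day 0, 9.99% ± 3.99 at day 4 and 54.4% ± 32.6 at day 7 (SD, n = 3). The single libraries, with Wilson 95% intervals that cover counting error only, gave 58.4% (58.3 to 58.6), 58.4% (58.3 to 58.6) and 62.2% (62.1 to 62.3) at day 0, 11.2% (11.2 to 11.3), 13.2% (13.2 to 13.3) and 5.52% (5.49 to 5.55) at day 4 and 90.4% (90.3002 to 90.5), 45.7% (45.6 to 45.8) and 27.0% (26.9 to 27.1) at day 7. Day 4 lay below days 0 and 7 in every library, with an exact permutation p of 0.1 (two-sided) in each comparison, the smallest that 3 against 3 libraries can give. Days 7 and 0 differed with an exact permutation p of 0.8 (two-sided). Without the ORFs above 0.5% of counts on average, the R79 share was 58.8% ± 2.404, 27.8% ± 9.29 and 64.0% ± 27.3 at days 0, 4 and 7, with the same exact permutation p-values. Shares of counts are not shares of cells.

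**Figure D1:**
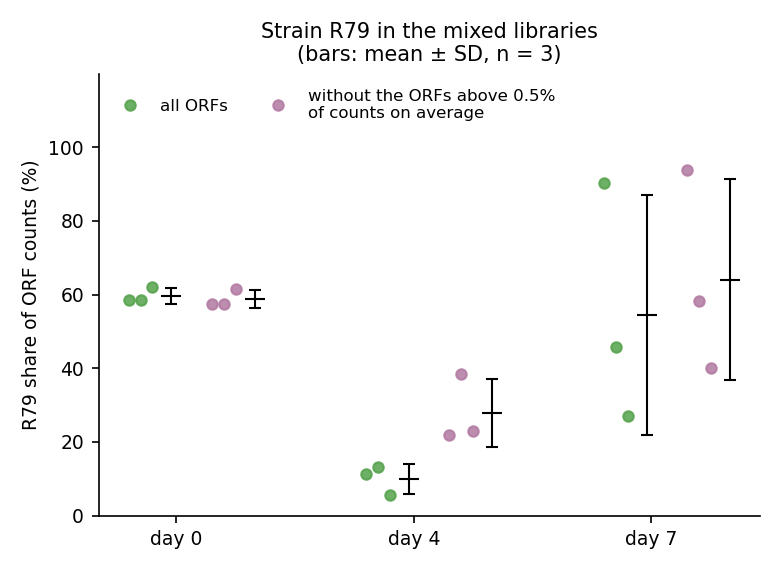
R79 share of ORF counts (%, vertical axis) in each mixed library by day, as points, with bars for mean ± SD of 3 libraries, over all ORFs (green) and without the ORFs above 0.5% of counts on average (violet). The 3 libraries of day 4 lie between 5.52% and 13.2% over all ORFs, and those of day 7 spread from 27.0% to 90.4%.

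A single stretch of the R90 ORF numbering, orf04174 to orf04288 with 115 ORFs, took up much of the R90 signal after day 0, in R90 alone and in co-culture. The stretch was chosen after its values were seen, and the tables give no coordinates, so that its ORFs are neighbours is taken from their numbers. Its 12 ORFs above 0.5% of counts on average held 0.103% ± 0.00754 of the R90 counts in R90 alone at day 0, 47.6% ± 10.5 at day 4 and 49.8% ± 4.94 at day 7 (SD, n = 3). In co-culture they held 0.127% ± 0.0435, 72.3% ± 13.2 and 46.1% ± 2.92. Between days 0 and 7, 98 of the 115 ORFs rose in R90 alone and 94 in co-culture, with no called fall. Named members with large rises were 2 plasmid-like proteins, orf04259 (log2 fold change 9.04 ± 0.63 alone and 9.92 ± 0.66 in co-culture) and orf04245 (8.37 ± 0.54 and 8.61 ± 0.56), and the chromosome partitioning protein orf04263 (8.39 ± 0.52 alone). At day 4 the 12 ORFs were higher in co-culture than in R90 alone by a median log2 fold change of 1.78 (range 0.56 to 2.31), with 10 called, but as deposited, without a library factor, that median was 0.59 with 1 called. At day 7 they differed by -0.71 to 1.02 and edgeR called 0 of the 12.

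**Figure D2:**
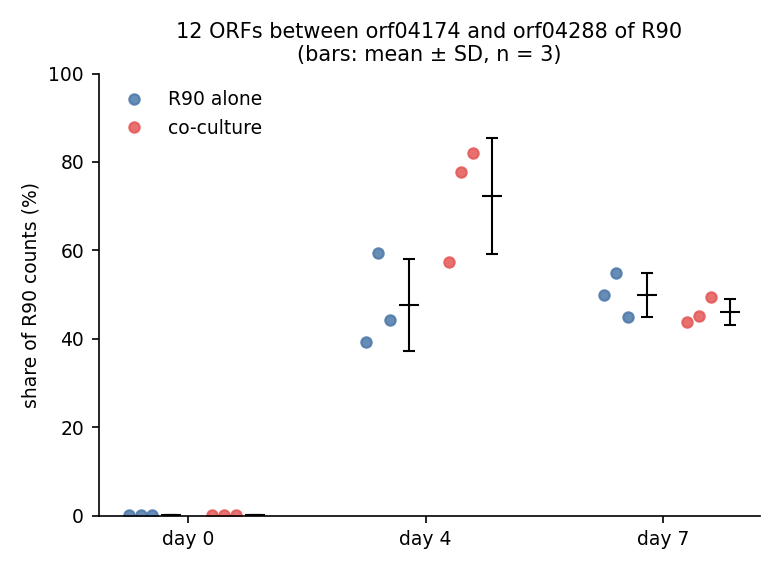
Share of R90 counts (%, vertical axis) held by 12 ORFs between orf04174 and orf04288 in each library, with R90 alone in blue and co-culture in red, and bars for mean ± SD of 3 libraries. The share lies between 0.0873% and 0.173% at day 0 and between 39.2% and 82.0% at days 4 and 7.

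Directly after mixing, the comparison of R79 in co-culture with R79 alone gives the state from which the cultures started. Isocitrate lyase (orf01929), the first enzyme of the glyoxylate shunt that bacteria need for growth on acetate, was lower in co-culture, at 712 ± 160.1 against 3010.2 ± 814 normalised RPKM (log2 fold change -2.08 ± 0.40, adjusted p = 0.0203). A protein of the Rickettsia 17 kDa surface antigen family (orf00362) was lower as well, at 1858 ± 253 against 5759.6 ± 1964 (log2 fold change -1.63 ± 0.30). The oxidative stress list had a median of -0.54 (camera adjusted p = 0.00228, 0.378 with an estimated correlation). Of its 11 genes, none was called (0 and 1 in the list). The wider ribosomal protein list had a median of 0.30 (camera adjusted p = 2.2e-04, 0.552 with an estimated correlation). Of its 54 genes, none was called (1 and 0 in the list). Below, p-values with an estimated correlation are marked as estimated, brackets after a list's counts give higher and lower genes after adjustment in the list alone where these differ, and other scalings are given where they moved a count by 2 or more and over 1.5-fold. edgeR called 8 genes, 1 higher and 7 lower, with 267 at an unadjusted p under 0.05. The 3 values per group did not overlap for 8 of the 8 and for 14.3% of all genes, where chance gives 10% here and below. The calls rested on single libraries, since the count was 0 without co-culture replicates 1, 2 and 3 and R79 alone replicate 2, 13 without R79 alone replicate 1 and 79 without R79 alone replicate 3. Where edgeR called 0, 196 to 228 genes had an unadjusted p under 0.05. Both named genes lost their call without each of co-culture replicates 1, 2 and 3 and R79 alone replicate 2. The split between higher and lower was 1 and 2 as deposited, without a library factor, and 1 and 1 quantile-normalized. limma on log2(RPKM + 1) called 0 with 240 at an unadjusted p under 0.05, and DESeq2 called 30. The median of all genes lay at 0.16 as deposited, and changes are relative to the scaled bulk of genes.

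At day 4 the transcripts of R79 differed broadly between co-culture and R79 alone. Higher in co-culture were single genes for protein folding, conjugation and phosphate uptake. Chaperonin GroL (orf00371), which folds newly made proteins, stood at 5095 ± 679.7 against 561 ± 98.0 normalised RPKM (log2 fold change 3.18 ± 0.30, adjusted p = 3.4e-07). Conjugal transfer protein TrbC (orf00575), a pilin-like part of conjugation systems, stood at 1481 ± 699.6 against 49.2 ± 43.7 (log2 fold change 4.64 ± 0.59), and its neighbour by number, a VirB3-like protein of type IV secretion (orf00576), at 1223 ± 501 against 51.3 ± 23.8 (4.39 ± 0.59). PstA (orf01935), a permease of high-affinity phosphate uptake, stood at 371 ± 97.8 against 44.0 ± 2.79 (3.06 ± 0.39). Lower in co-culture were a phasin family protein (orf02608), the kind that coats polyhydroxyalkanoate storage granules, at 240.2 ± 54.3 against 5359 ± 3825 (-4.45 ± 0.60, adjusted p = 1.9e-05), and the plasmid maintenance proteins of a killer (orf00609, 1277 ± 274 against 20502 ± 9795, -4.01 ± 0.41) and its antidote (orf00610, 879 ± 313 against 9620.3 ± 4792, -3.43 ± 0.42).

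The other largest R79 rises at day 4 were an FAD dependent oxidoreductase (orf02338, log2 fold change 3.65), a metallo-beta-lactamase superfamily protein (orf02340, 3.17) and a helix-turn-helix protein (orf02062, 3.17). Methylmalonate-semialdehyde dehydrogenase (orf02061, 3.10), which acts in valine breakdown, a lytic transglycosylase (orf02731, 3.06), which cuts peptidoglycan, and a type III secretion system protein (orf02723, 3.02) were higher too. The other largest falls were a plasmid stabilization system protein (orf03197, -4.54), an ArsR family regulator (orf00394, -4.34) and a putative membrane protein with the next number (orf00395, -3.74). A dnaA domain-containing protein (orf01783, -4.14), a helix-turn-helix domain-containing protein (orf03198, -3.70), an NmrA family protein (orf00593, -3.54) and a SAM-dependent methyltransferase (orf01399, -3.51) were lower too. All 20 of these named genes kept their call in all leave-one-out fits.

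Among the gene lists, that of the respiratory chain had the lowest camera p at day 4 in R79. The ATP synthase and respiratory chain list had a median of 1.01 (camera adjusted p = 2.0e-08, 0.378 estimated). Of its 37 genes, 19 were higher. The higher genes included the ATP synthase B/B' protein (orf02314, 2.55 ± 0.40), the epsilon chain (orf00458, 2.17 ± 0.50) and the C chain (orf02313, 1.98 ± 0.34). Subunit H of NADH-quinone oxidoreductase (orf01173, 2.20 ± 0.33) was another. The ribosomal protein list as fixed beforehand had a median of 0.87 (1.52 quantile-normalized, camera adjusted p = 0.0283, 0.479 estimated). Of its 7 genes, 2 were higher (3 and 0 in the list, 4 and 0 as deposited, 6 and 0 quantile-normalized). The wider list of ribosomal proteins had a median of 0.89 (camera adjusted p = 3.7e-05, 0.482 estimated). Of its 54 genes, 23 were higher and 2 lower (24 and 2 in the list, 31 and 0 quantile-normalized). Among the higher ones were S1 (orf01650, 2.36), S16 (orf00060, 2.22), L7/L12 (orf01095, 1.89) and L11 (orf01102, 1.79). The cobalamin and B vitamin list had a median of 0.57 (camera adjusted p = 0.0351, 0.378 estimated). Of its 18 genes, 5 were higher and 1 lower (6 and 1 in the list). The vitamin B12 transporter BtuB (orf01727, 2.60) and the thiazole synthesis protein ThiG (orf01010, 2.15) were higher. The prophage and mobile element list of R79 had a median of -0.67 (camera adjusted p = 0.0125, 0.418 estimated). Of its 44 genes, 7 were lower.

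The lists that camera did not call in R79 at day 4 still held called genes. Phosphate starvation had a median of 0.37 (camera adjusted p = 0.0732, not called). Of its 16 genes, 5 were higher and 1 lower. The permease PstC (orf01934, 2.27) and the ATP-binding protein (orf01936, 1.59) of phosphate uptake were higher beside PstA. The list of secretion systems of type VI, III and IV had a median of 0.75 (camera adjusted p = 0.0610, not called). Of its 8 genes, 4 were higher and 1 lower. The acetate, glyoxylate shunt and TCA cycle list had a median of 0.36 (camera adjusted p = 0.359, not called). Of its 16 genes, 3 were higher and 2 lower. Both enzymes of the glyoxylate shunt were lower, isocitrate lyase (orf01929, -1.75 ± 0.39) and malate synthase G (orf02005, -1.18 ± 0.29), while aconitate hydratase 1 (orf00213) was higher by 1.75 ± 0.28. Nitrogen assimilation had a median of -0.08 (0.01 as deposited, camera adjusted p = 0.481, not called). Of its 8 genes, 2 were lower. The lower ones were the small chain of glutamate synthase (orf02704, -2.41) and the nitrogen regulatory protein P-II (orf00814, -1.68). Iron uptake had a median of -0.30 (camera adjusted p = 0.720, not called). Of its 68 genes, 6 were higher and 8 lower (8 and 4 as deposited, 10 and 7 quantile-normalized). Flagellum and chemotaxis had a median of -0.03 (0.14 as deposited, camera adjusted p = 0.792, not called). Of its 47 genes, 3 were higher and 5 lower (2 and 5 in the list, 4 and 3 as deposited). The chaperone and protease list had a median of -0.05 (0.09 as deposited, camera adjusted p = 0.573, not called). Of its 27 genes, 2 were higher and 2 lower. Oxidative stress had a median of 0.08 (camera adjusted p = 0.938, not called). Of its 11 genes, 2 were higher. An AhpC/TSA family protein (orf02341, 2.04) and manganese superoxide dismutase (orf02442, 1.75), both of which remove reactive oxygen, were higher.

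Of the 53 called list members of day 4, 45 kept their call in all leave-one-out fits, and the calls lost were 7 without R79 alone replicate 3, 6 without co-culture replicate 1, 5 without R79 alone replicate 1 and co-culture replicate 2 and 3 without co-culture replicate 3. edgeR called 736 of 3198 R79 genes at day 4, 370 higher and 366 lower in co-culture. The 3 values per group did not overlap for 661 of them and for 37.8% of all genes. As deposited the split was 461 higher and 305 lower, with the median of all genes at 0.11.

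At day 7 fewer R79 genes set co-culture apart from R79 alone, and 2 chaperonins and 2 dehydrogenases were among the higher ones. An acetyltransferase of the GNAT family (orf02231) stood at 3774 ± 637 against 586 ± 62.7 normalised RPKM (log2 fold change 2.69 ± 0.32, adjusted p = 7.7e-05). The 10 kDa chaperonin (orf00370) stood at 2773 ± 981 against 515 ± 50.6 (log2 fold change 2.43 ± 0.33) and its partner GroL (orf00371) at 3645 ± 702 against 928 ± 149 (1.97 ± 0.28). A membrane-bound PQQ-dependent glucose or quinate dehydrogenase (orf00016) stood at 1463 ± 460.0 against 353 ± 5.41 (2.05 ± 0.28) and L-sorbosone dehydrogenase (orf01422) at 1384 ± 398 against 329 ± 57.8 (2.07 ± 0.31). Lower were a plasmid stabilization system protein (orf03197, 188 ± 159.8 against 1515 ± 788, -2.99 ± 0.54) and the N-acetylglucosamine deacetylase of lipid A synthesis (orf02479, 129 ± 25.7 against 704 ± 367, -2.45 ± 0.46, adjusted p = 0.00306).

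The remaining large R79 rises at day 7 were a hemolysin-III related protein (orf03155, log2 fold change 2.22), a helix-turn-helix protein (orf01928, 2.08) and an M50 family peptidase (orf01555, 2.03). A ribonuclease HII family protein (orf02385, 2.02) and the biosynthetic threonine ammonia-lyase (orf01551, 1.97), which starts isoleucine synthesis, were higher too. The remaining falls were a MutT/nudix family protein (orf00459, -2.82), type II secretion system protein C (orf02045, -2.14), the ArsR family regulator orf00394 (-2.02) and the membrane protein orf00395 (-1.72). A helix-turn-helix domain-containing protein (orf03198, -1.86), alanine racemase (orf00650, -1.80), a flagellin FljK (orf02145, -1.79) and a beta/gamma crystallin domain protein (orf01963, -1.61) were lower too. Of the 20 named genes, 14 kept their call in all leave-one-out fits. The calls lost were 5 without co-culture replicate 2, 4 without R79 alone replicates 2 and 3 and co-culture replicates 1 and 3 and 2 without R79 alone replicate 1.

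In R79 at day 7 the chaperone and protease list had a median of 0.50 (0.22 as deposited, camera adjusted p = 2.2e-04, 0.378 estimated). Of its 27 genes, 5 were higher (2 and 0 as deposited, 2 and 0 quantile-normalized). Oxidative stress had a median of 0.34 (0.05 as deposited and 0.09 quantile-normalized, camera adjusted p = 0.0236, 0.378 estimated). Of its 11 genes, 3 were higher. Catalase (orf02915, 1.698 ± 0.29) and an organic hydroperoxide resistance protein (orf01304, 1.62 ± 0.32) were higher. Osmotic stress and compatible solutes had a median of 0.29 (0.00 as deposited, camera adjusted p = 0.0291, 0.378 estimated). Of its 12 genes, 2 were higher (0 and 0 as deposited, 0 and 0 quantile-normalized). The flagellum and chemotaxis list had a median of -0.24 (camera adjusted p = 0.0246, 0.479 estimated). Of its 47 genes, 3 were lower. The lower ones included hook-associated protein FlgK (orf01994, -1.60 ± 0.33), which joins hook and filament. The acetate list of R79 had a median of 0.16 (-0.12 as deposited, camera adjusted p = 0.953, not called). Of its 16 genes, 1 was higher and 2 lower. Malate synthase G (orf02005, -1.36 ± 0.29) was again lower. The respiratory list of R79 had a median of 0.23 (-0.05 as deposited, camera adjusted p = 0.0619, not called). Of its 37 genes, 1 was higher. Of the 22 called list members here, 6 kept their call in all leave-one-out fits, and the calls lost were 13 without R79 alone replicate 2 and co-culture replicate 2, 12 without R79 alone replicate 3, 8 without R79 alone replicate 1, 6 without co-culture replicate 1 and 4 without co-culture replicate 3. Of the 17 higher members among them, 11 were not called as deposited and 11 quantile-normalized.

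edgeR called 153 R79 genes at day 7, 115 higher and 38 lower, without overlap for 148 of them and for 28.8% of all genes. The split turned with the scaling, to 56 higher and 105 lower as deposited, where the median of all genes lay at -0.30. With quantile normalization it was 46 higher and 27 lower. The count was 56 without co-culture replicate 2, 61 without R79 alone replicate 2 and 58 without R79 alone replicate 3.

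**Figure D3:**
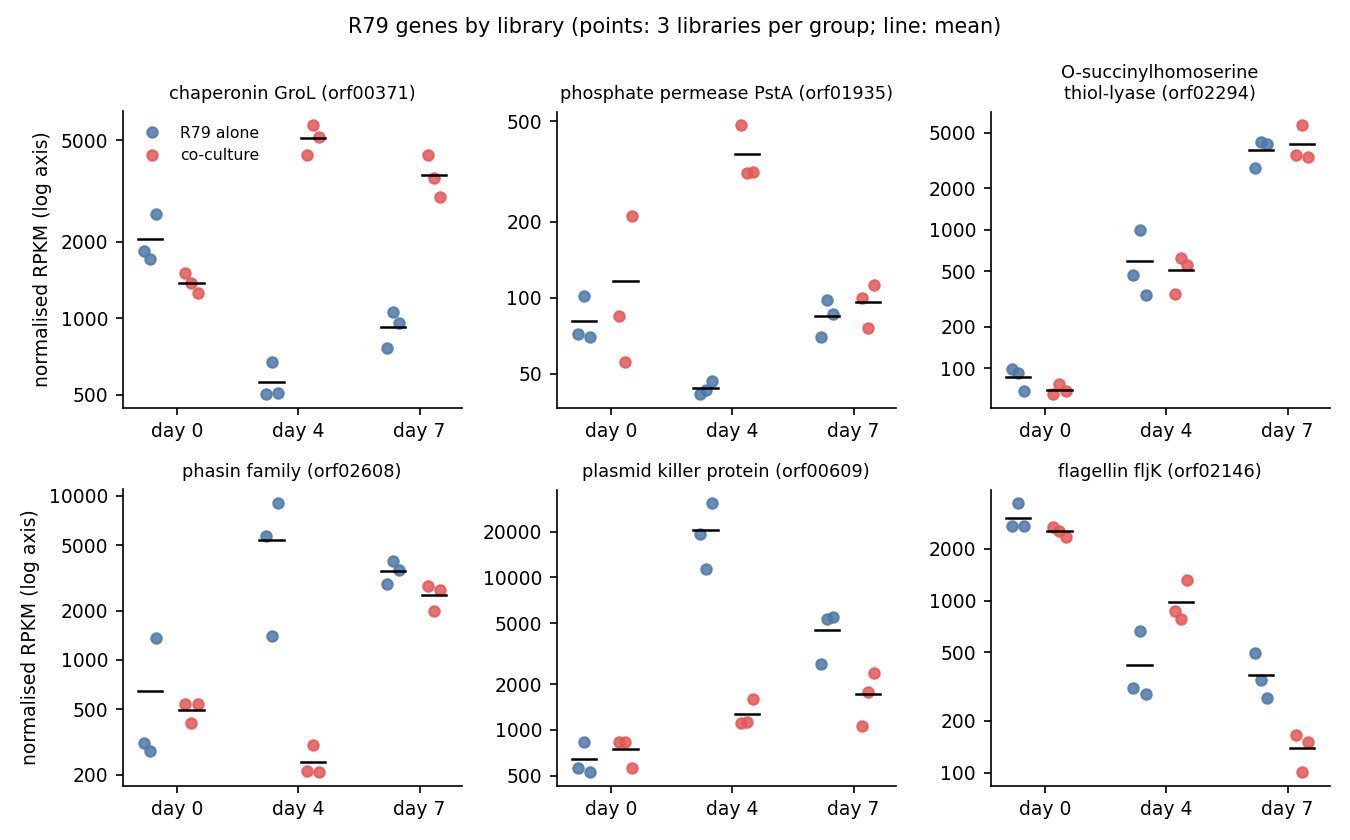
Normalised RPKM (log axis) of 6 named R79 genes by day in R79 alone (blue) and co-culture (red), with 1 point per library and lines for the means of 3. Chaperonin GroL stands at 5095 ± 679.7 (co-culture) against 561 ± 98.0 (alone) at day 4, and O-succinylhomoserine thiol-lyase lies between 2793 and 5703 at day 7 in both cultures.

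Between days 0 and 7, R79 alone raised O-succinylhomoserine thiol-lyase and genes for ammonium assimilation. The lyase (orf02294), an enzyme of methionine synthesis, went from 86.8 ± 16.3 to 3743 ± 827 normalised RPKM (log2 fold change 5.43 ± 0.42, adjusted p = 1.0e-08). The next ORF, an alpha/beta hydrolase fold protein (orf02295), rose by 5.21 ± 0.51, a TonB dependent receptor (orf01066) by 4.63 ± 0.59 and a plasmid stabilization system protein (orf03197) by 4.42 ± 0.57 on the log2 scale. A BFD-like 2Fe-2S protein (orf01975) rose from 2 to 19 counts over the groups, a ratio of 25.9 (counting interval 6.25 to 229). The largest falls were a LysM domain protein (orf02709, -4.57 ± 0.40), a phospholipase (orf02706, -3.96 ± 0.45), an entericidin EcnA/B family protein (orf02895, -3.75), a metallo-beta-lactamase superfamily protein (orf02340, -3.34) and a SURF1 family protein (orf02011, -3.24). All 10 kept their call in all leave-one-out fits.

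Nitrogen assimilation of R79 alone had a median of 1.47 (camera adjusted p = 2.2e-04, 0.378 estimated). Of its 8 genes, 5 rose. The glutamate synthase genes orf02704 (4.04 ± 0.38) and orf02703 (3.23 ± 0.35) and glutamine synthetase (orf00815, 1.72 ± 0.25), which take up ammonium, rose. Amino acid biosynthesis by enzyme name had a median of 0.16 (camera adjusted p = 0.0351, 0.378 estimated). Of its 59 genes, 12 rose and 2 fell (12 and 1 in the list). The rises included 3-isopropylmalate dehydratase (orf00008, 3.74) of leucine synthesis. The ribosomal protein list had a median of 1.39 (camera adjusted p = 0.00214, 0.378 estimated). Of its 7 genes, 5 rose. The wider ribosomal protein list had a median of 0.99 (camera adjusted p = 1.0e-08, 0.389 estimated). Of its 54 genes, 25 rose. Iron uptake in R79 alone had a median of 0.51 (camera adjusted p = 0.00773, 0.479 estimated). Of its 68 genes, 15 rose and 5 fell. The prophage and mobile element list had a median of 0.67 (camera adjusted p = 0.0236, 0.479 estimated). Of its 44 genes, 12 rose (11 and 0 in the list, 6 and 0 quantile-normalized). The oxidative stress list had a median of -1.40 (camera adjusted p = 0.00996, 0.378 estimated). Of its 11 genes, 6 fell. The falls included the AhpC/TSA protein orf02341 (-2.36 ± 0.44) and manganese superoxide dismutase (orf02442, -2.24 ± 0.27). edgeR called 827 genes in R79 alone, 400 higher and 427 lower at day 7, without overlap for 767 of them and for 42.7% of all genes.

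In co-cultured R79, the lyase orf02294 rose between days 0 and 7 by 5.90 ± 0.44 and the hydrolase orf02295 by 5.43 ± 0.51 on the log2 scale. An aspartate/glutamate/uridylate kinase (orf02297), of a family that includes the first enzyme of the aspartate pathway, rose by 5.15 ± 0.37. TrbC (orf00575) went from 13.8 ± 16.6 to 1655 ± 831 normalised RPKM (log2 fold change 7.05 ± 0.70, adjusted p = 1.6e-07), and the VirB3-like orf00576 rose by 4.82 ± 0.62. Flagellin FljK (orf02146), the protein of the filament, fell from 2522 ± 156 to 139 ± 33.8 (log2 fold change -4.18 ± 0.37). The other large falls were a PadR-like regulator (orf01662, -4.06 ± 0.80), a putative membrane protein (orf02449, -3.98 ± 1.10) and a nifU-like protein (orf03139, -3.65 ± 0.52). An ASCH domain protein (orf01724) went from 52 to 2 counts over the groups, a ratio of 0.0483 (counting interval 0.00570 to 0.183). All 10 kept their call in all leave-one-out fits.

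Nitrogen assimilation in co-cultured R79 had a median of 1.53 (camera adjusted p = 2.2e-04, 0.378 estimated). Of its 8 genes, 5 rose. Glutamate synthase (orf02703) rose by 4.07 ± 0.36 and an ammonium transporter (orf02702) by 1.69 ± 0.31 on the log2 scale. Amino acid biosynthesis by enzyme name had a mean of 0.57 and an upward camera test (adjusted p = 0.0241, 0.378 estimated), while its median was -0.09 (0.01 quantile-normalized). Of its 59 genes, 15 rose and 1 fell (14 and 8 as deposited). Iron uptake in co-cultured R79 had a median of 0.55 (0.16 as deposited, camera adjusted p = 0.0283, 0.552 estimated). Of its 68 genes, 19 rose and 7 fell (9 and 10 as deposited). The ribosomal protein list had a median of 1.02 (camera adjusted p = 0.0179, 0.479 estimated). Of its 7 genes, 3 rose (4 and 0 in the list). The wider ribosomal protein list had a median of 0.69 (0.29 as deposited, camera adjusted p = 0.00201, 0.575 estimated). Of its 54 genes, 21 rose and 1 fell (12 and 3 as deposited, 12 and 1 quantile-normalized). edgeR called 1011 genes in co-culture, 535 higher and 476 lower at day 7, without overlap for 996 of them and for 57.1% of all genes. As deposited the split was 320 higher and 835 lower, with the median of all genes at -0.40.

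Whether the difference between co-culture and R79 alone changed from day 0 to day 7 was tested as an interaction. The GNAT acetyltransferase orf02231 stood at 3774 ± 637 in co-culture against 586 ± 62.7 alone at day 7, and at 545 ± 86.6 against 658 ± 81.5 at day 0 (interaction 2.96 ± 0.44 on the log2 scale, adjusted p = 5.8e-04). The PQQ-dependent dehydrogenase orf00016 (2.85 ± 0.39) and a response regulator (orf02891, 3.04 ± 0.50) moved the same way, and type II secretion system protein C (orf02045, -3.50 ± 0.77) the other way. edgeR called 155 genes, 133 positive and 22 negative, with non-overlapping differences for 144 of them and for 11.9% of all genes (chance share not 10%, not computed). The signs turned as deposited, with 68 positive and 105 negative and the median of all genes at -0.48. The count was 94 without day 0 co-culture replicate 1, 100 without day 0 co-culture replicate 3, 73 without day 7 co-culture replicate 2, 246 without day 0 R79 alone replicate 3, 91 without day 7 R79 alone replicate 2 and 98 without day 7 R79 alone replicate 3.

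For R90 directly after mixing, both subunits of tryptophan synthase, the last enzyme of tryptophan synthesis, were higher in co-culture than alone. The beta subunit (orf03965) stood at 486 ± 286 against 26.6 ± 4.70 normalised RPKM (log2 fold change 4.21 ± 0.48, adjusted p = 4.2e-05). The alpha subunit (orf03966) stood at 406 ± 227 against 30.1 ± 6.10 (3.76 ± 0.46, adjusted p = 7.5e-05). A metal transporting P-type ATPase (orf03054, 78.2 ± 7.02 against 739 ± 299, -3.24 ± 0.65) and a metal transporter (orf00391, 119 ± 52.3 against 1092 ± 227, -3.20 ± 0.57) were lower. Flavohemoglobin (orf03942, 69.6 ± 20.0 against 239 ± 19.3, -1.78 ± 0.30), which detoxifies nitric oxide, was lower as well. The prophage list had a median of -0.54 (camera adjusted p = 0.00251, 0.709 with an estimated correlation). Of its 48 genes, none was called. Sulfate assimilation and sulfonates had a median of -0.46 (-0.19 quantile-normalized, camera adjusted p = 0.0429, 0.709 with an estimated correlation). Of its 15 genes, none was called. Denitrification had a median of 0.05 (camera adjusted p = 0.0331, 0.709 with an estimated correlation). Of its 28 genes, none was called (2 and 0 in the list). edgeR called these 5 genes, 2 higher and 3 lower, with 406 at an unadjusted p under 0.05. The 3 values per group did not overlap for all 5 and for 20.1% of all genes. The tryptophan synthase genes kept their call in all leave-one-out fits. The calls lost among the 5 were 3 without R90 alone replicate 2 and co-culture replicates 2 and 3, 2 without co-culture replicate 1 and 1 without R90 alone replicate 3, and the count was 3 without co-culture replicate 1 and 2 without co-culture replicates 2 and 3 and R90 alone replicate 2. The split was 2 higher and 2 lower as deposited, 2 and 1 quantile-normalized and 2 and 1 with limma on log2(RPKM + 1).

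At day 4, R90 in co-culture had higher transcripts than R90 alone for 3 enzymes of ectoine synthesis and lower ones for leucine dehydrogenase, cytochrome c-551 and NirL. Diaminobutyrate 2-oxoglutarate aminotransferase (orf03453), the first enzyme of ectoine synthesis, stood at 1092 ± 290.3 against 181 ± 53.4 normalised RPKM (log2 fold change 2.59 ± 0.39, adjusted p = 1.4e-04). The acetyltransferase of the next step (orf03452) stood at 1085 ± 213 against 207 ± 100.0 (2.39 ± 0.41), and ectoine synthase (orf03451) at 533 ± 117 against 112 ± 36.6 (2.26 ± 0.40). Isocitrate lyase (orf01907) was higher, at 989 ± 252 against 208 ± 104 (2.25 ± 0.50). Leucine dehydrogenase (orf00630), which removes the amino group of branched-chain amino acids, was lower at 15.0 ± 3.96 against 447 ± 374 (-4.92 ± 0.71, adjusted p = 1.1e-04). Cytochrome c-551 (orf00581), an electron carrier to nitrite reductase, was lower at 28.8 ± 11.5 against 851 ± 1113 (-4.86 ± 1.01), and the heme d1 biosynthesis protein NirL (orf00577) at 9.23 ± 4.82 against 154 ± 165 (-3.93 ± 0.91).

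The other largest R90 rises at day 4 were FxsA (orf03777, log2 fold change 2.91), a stress induced hydrophobic peptide (orf02333, 2.85), a putative amino acid permease (orf01435, 2.82) and D-3-phosphoglycerate dehydrogenase of serine synthesis (orf00934, 2.48). An oxidase (orf04043, 2.46), a periplasmic serine protease of the ClpP class (orf02442, 2.43), a short chain dehydrogenase (orf03595, 2.34) and glutaryl-CoA dehydrogenase (orf00978, 2.31) were higher too. The other largest falls were a maltose transporter protein (orf00560, -4.41), a periplasmic alpha-amylase (orf00561, -4.05) and a c-type cytochrome (orf00580, -4.36). An oligopeptide-binding protein (orf02191, -4.33), indolepyruvate ferredoxin oxidoreductase (orf00632, -4.13) and cytochrome b561 (orf01744, -3.99) were lower too. Muconolactone delta-isomerase (orf02088) had 2 counts over the co-culture group and 48 over R90 alone, a ratio of 0.0651 (counting interval 0.00766 to 0.248). Of the 20 named genes, 17 kept their call in all leave-one-out fits, and the calls lost were 2 without R90 alone replicate 2 and co-culture replicate 2 and 1 without R90 alone replicate 3 and co-culture replicates 1 and 3. As deposited (median of all genes -0.99), 9 of 10 rises, all falls and only 7 of 25 higher list members stayed called.

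The osmotic stress list of R90 at day 4 had a median of 0.82 (-0.22 as deposited, camera adjusted p = 0.0186, 0.451 estimated). Of its 23 genes, 7 were higher and 2 lower (7 and 3 in the list, 1 and 5 as deposited). The higher ones included subunit MnhF (orf01454, 2.16 ± 0.41) of a Na+/H+ antiporter and the antiporter NhaD (orf02490, 1.74 ± 0.27). Prophage and mobile elements had a median of 0.26 (-0.78 as deposited, camera adjusted p = 0.0170, 0.709 estimated). Of its 48 genes, 13 were higher and 2 lower (4 and 13 as deposited). A phage tail tube protein (orf04208, 2.30 ± 0.37) and a phage related DNA methyltransferase (orf02428, 2.20 ± 0.47) were higher, and a transposase of ISPsy21 (orf00711, -3.08 ± 0.56) was lower. Denitrification had a median of -0.76 (-1.76 as deposited, camera adjusted p = 0.0587, not called). Of its 28 genes, 1 was higher and 6 lower (1 and 7 in the list, 0 and 19 as deposited, 1 and 2 quantile-normalized). NirF (orf00579, -3.41 ± 0.78), of heme d1 synthesis, and NarJ (orf00132, -3.38 ± 0.44), a chaperone of nitrate reductase, were lower. The respiratory list had a median of -0.04 (-1.07 as deposited and 0.04 quantile-normalized, camera adjusted p = 0.834, not called). Of its 38 genes, 5 were higher and 7 lower (0 and 17 as deposited, 3 and 5 quantile-normalized). A cbb3-type cytochrome c oxidase protein (orf03214, -2.395 ± 0.57), of an oxidase with high oxygen affinity, and cytochrome c oxidase subunit II (orf04163, -1.93 ± 0.43) were lower. Multidrug efflux and antimicrobials had a median of -0.32 (-1.22 as deposited, camera adjusted p = 0.189, not called). Of its 28 genes, 5 were lower (0 and 13 as deposited, 0 and 3 quantile-normalized). The pump protein TtgB (orf02279, -1.53) and the outer membrane protein OprM (orf02280, -1.28) were lower. The chaperone and protease list had a median of 0.36 (-0.62 as deposited, camera adjusted p = 0.125, not called). Of its 36 genes, 7 were higher and 2 lower (1 and 12 as deposited). Co-chaperonin GroES (orf03779, 1.61) was higher. Of the 50 called list members of R90 at day 4, 27 kept their call in all leave-one-out fits, and the calls lost were 13 without co-culture replicate 3, 12 without R90 alone replicate 1 and co-culture replicate 2, 9 without R90 alone replicate 2, 5 without R90 alone replicate 3 and 4 without co-culture replicate 1.

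edgeR called 864 of 4288 R90 genes at day 4, 396 higher and 468 lower, without overlap for 752 of them and for 35.7% of all genes. The split depended on the library factor, with 48 higher and 1756 lower as deposited, so the changes are relative to the scaled bulk of R90 genes. The 12 ORFs of the stretch described above took 72.3% ± 13.2 of the counts in co-culture and 47.6% ± 10.5 alone (SD, n = 3). limma on log2(RPKM + 1) called 292, 155 higher and 137 lower.

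At day 7, R90 in co-culture had higher transcripts than alone for flagellin type B, an adhesin-like protein, a porin and isocitrate lyase, and lower ones for a putative transmembrane protein and an ABC transporter. Flagellin type B (orf03194), a protein of the flagellar filament, stood at 1443 ± 635 against 251 ± 16.4 normalised RPKM (log2 fold change 2.51 ± 0.46, adjusted p = 0.00275). An outer membrane adhesin-like protein (orf02403) stood at 9237 ± 1816 against 2176 ± 480.0 (2.09 ± 0.42), a periplasmic protein (orf00266) at 1723 ± 947 against 245 ± 66.7 (2.74 ± 0.40) and a porin (orf01104) at 476 ± 55.1 against 111 ± 32.5 (2.09 ± 0.43). Isocitrate lyase (orf01907) stood at 4041 ± 1435 against 996 ± 797 (2.02 ± 0.50). The transmembrane protein orf04157 was lower at 93.4 ± 26.3 against 1084 ± 459 (-3.37 ± 0.49, adjusted p = 3.0e-04) and the ABC transporter orf00011 at 30.4 ± 17.7 against 325 ± 196 (-3.29 ± 0.53).

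The other largest R90 rises at day 7 were GlcG (orf00970, log2 fold change 2.08), phospho-2-dehydro-3-deoxyheptonate aldolase, the first enzyme of aromatic amino acid synthesis (orf01922, 2.04), and a methyl-accepting chemotaxis transducer (orf01168, 1.98). A phage integrase family protein (orf02628, 1.95) and peptide deformylase (orf03815, 1.89) were higher too. The other falls were the heme d1 genes NirL (orf00577, -4.12) and NirF (orf00579, -3.34) and genes close to 0 in co-culture. The nitrite reductase heme biosynthesis H protein (orf00575) had 1 count over the co-culture group, a ratio of 0.0263 to R90 alone (counting interval 0.000663 to 0.147). A redox-active disulfide protein (orf02670) had 2, a ratio of 0.0682 (0.00821 to 0.249), and a sodium-dependent transporter (orf00629) 3, a ratio of 0.0978 (0.0200 to 0.289). General secretion pathway protein I (orf03442) had 2, a ratio of 0.0971 (0.0117 to 0.356). Chemotaxis protein orf00843 had 1, a ratio of 0.0827 (0.00207 to 0.471). Quantile-normalized it reversed, with 4 of 10 falls and 8 of 10 rises called. An ArsR family regulator (orf02673) had 0 counts in co-culture and was at least 5.08-fold lower, from a floor of 3 counts over the group. Of the 20 named genes 7 kept their call in all leave-one-out fits, and the calls lost were 12 without co-culture replicate 3, 10 without co-culture replicate 2, 9 without R90 alone replicate 3, 4 without co-culture replicate 1, 2 without R90 alone replicate 2 and 1 without R90 alone replicate 1.

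The acetate list of R90 at day 7 had a median of 0.70 (camera adjusted p = 8.6e-07, 0.394 estimated). Of its 21 genes, 4 were higher (5 and 0 in the list, 2 and 0 quantile-normalized). Type II citrate synthase (orf03188, 1.67 ± 0.42) and isocitrate dehydrogenase (orf01898, 1.51 ± 0.35) of the TCA cycle were higher. Both lost their call without co-culture replicate 3 and R90 alone replicate 3, and isocitrate lyase without co-culture replicate 3 and R90 alone replicates 2 and 3. The ribosomal protein list had a median of 0.68 (camera adjusted p = 1.4e-07, 0.709 estimated). Of its 59 genes, 6 were higher (8 and 0 in the list, 0 and 0 as deposited, 1 and 0 quantile-normalized). The wider list of 60 had the same calls and a median of 0.68 (camera adjusted p = 1.4e-07, 0.709 estimated). Pili, adhesion and tight adherence had a median of 0.57 (camera adjusted p = 0.00500, 0.709 estimated). Among its 28 genes, 2 were higher (4 and 0 in the list, 0 and 0 as deposited, 4 and 0 quantile-normalized). The prophage list had a median of 0.20 (camera adjusted p = 0.0429, 0.709 estimated). Of its 48 genes, 1 was higher. The respiratory list had a median of 0.20 (camera adjusted p = 0.0631, not called). Of its 38 genes, 4 were higher and 1 lower (5 and 2 in the list, 1 and 2 as deposited, 2 and 0 quantile-normalized). Subunit I of the cytochrome d ubiquinol oxidase (orf01927, 2.13 ± 0.39), an oxidase for low oxygen, was higher. Iron uptake had a median of -0.04 (0.13 quantile-normalized, camera adjusted p = 0.213, not called). Of its 31 genes, 3 were higher (1 and 0 as deposited). Bacterioferritin (orf02549, 1.83 ± 0.35), an iron store, was higher. Flagellum and chemotaxis had a median of -0.00 (0.32 quantile-normalized, camera adjusted p = 0.190, not called). Of its 90 genes, 6 were higher and 5 lower (7 and 5 in the list, 3 and 1 as deposited, 8 and 3 quantile-normalized). Denitrification had a median of -0.03 (0.70 quantile-normalized, camera adjusted p = 0.974, not called). Among its 28 genes, 3 were lower. Of the 37 called list members of R90 at day 7, 4 kept their call in all leave-one-out fits, and the calls lost were 29 without R90 alone replicate 3 and co-culture replicate 3, 23 without co-culture replicate 2, 12 without R90 alone replicate 2, 7 without co-culture replicate 1 and 6 without R90 alone replicate 1.

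edgeR called 390 R90 genes at day 7, 140 higher and 250 lower, without overlap for 333 of them and for 31.0% of all genes. The split was 38 higher and 125 lower as deposited and 68 higher and 321 lower with limma on log2(RPKM + 1). The median of all genes lay at -0.12, and at -0.23 as deposited, 0.06 quantile-normalized and -0.52 with that limma fit. The count was 155 without co-culture replicate 2, 107 without co-culture replicate 3 and 112 without R90 alone replicate 3, and 406 without co-culture replicate 1, the library of 39421 counts.

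**Figure D4:**
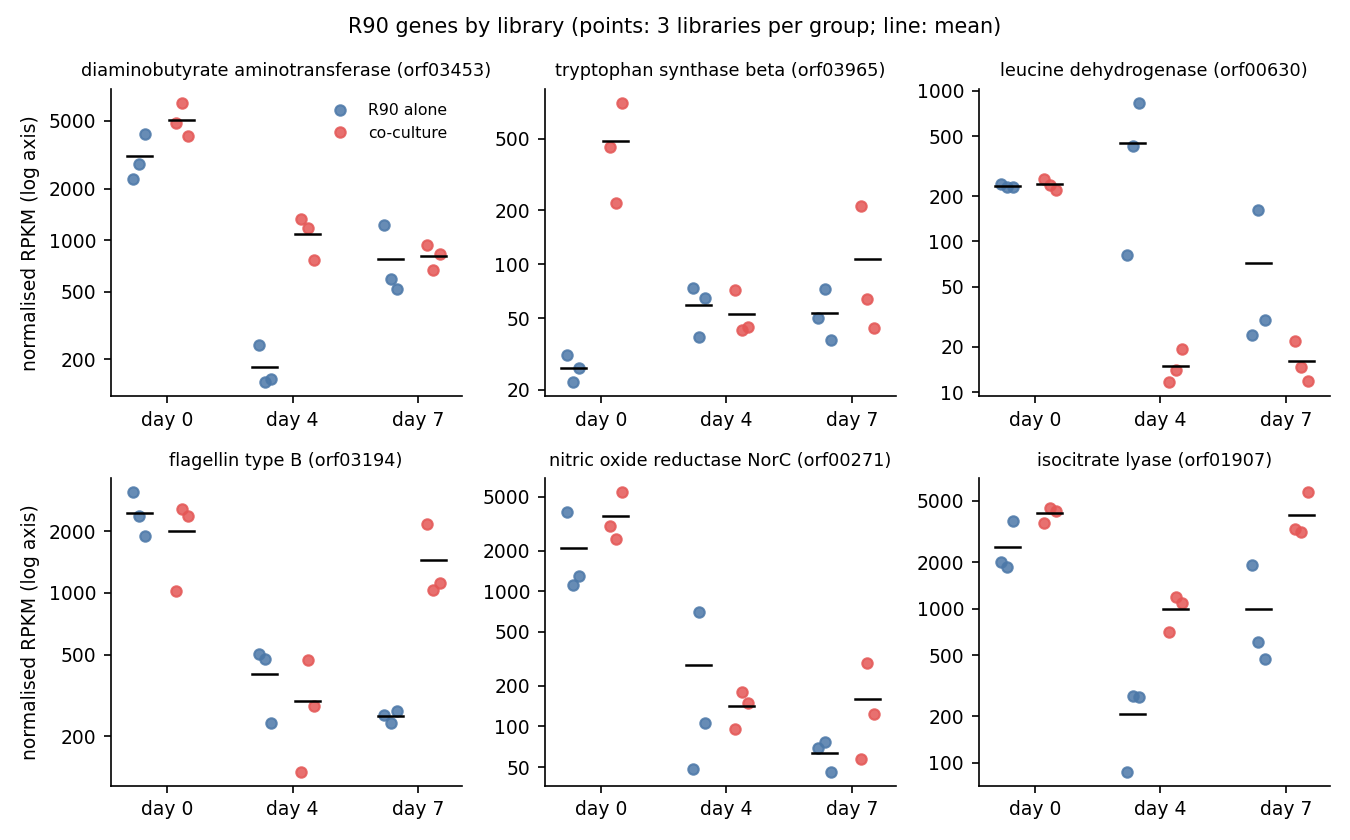
Normalised RPKM (log axis) of 6 named R90 genes by day in R90 alone (blue) and co-culture (red), with 1 point per library and lines for the means of 3. Leucine dehydrogenase stands at 15.0 ± 3.96 (co-culture) against 447 ± 374 (alone) at day 4, and flagellin type B at 1443 ± 635 (co-culture) against 251 ± 16.4 (alone) at day 7.

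**Figure D5:**
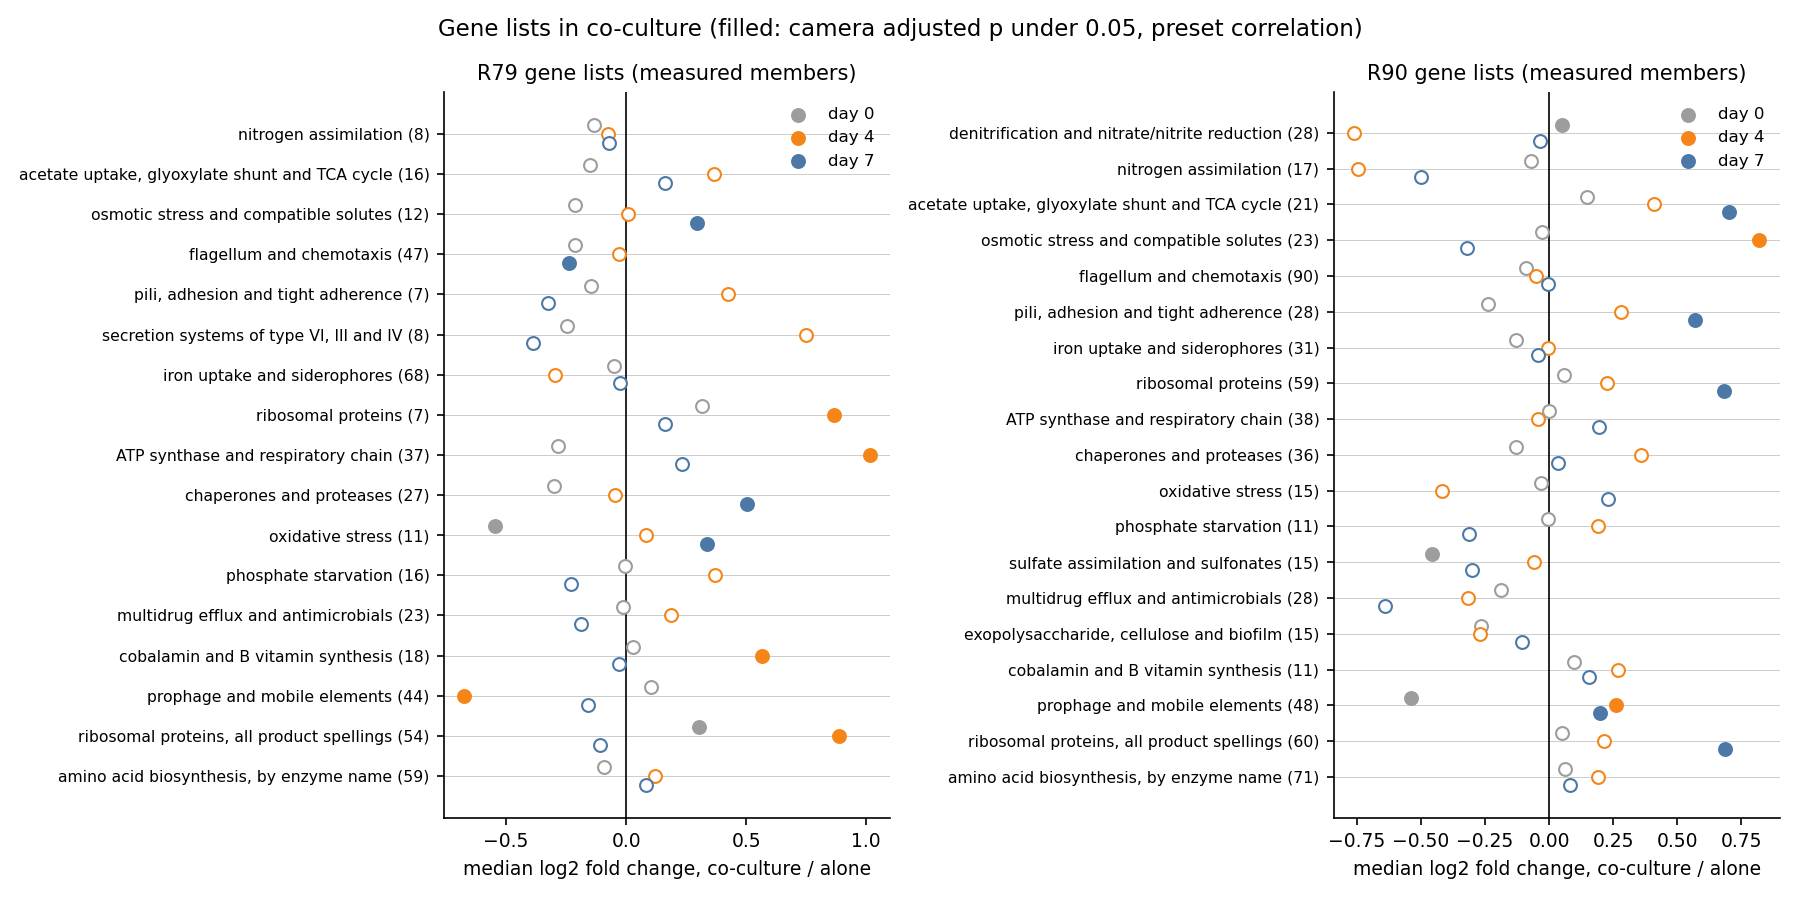
Median log2 fold change of co-culture against alone (horizontal axis) of each gene list in R79 (left) and R90 (right) at days 0, 4 and 7, with filled points where camera with a preset correlation gave an adjusted p under 0.05. The respiratory list of R79 lies at 1.01 at day 4 and the acetate list of R90 at 0.70 at day 7, while the osmotic list of R90 at day 4, at 0.82, lies at -0.22 as deposited.

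Between days 0 and 7, R90 alone raised most ORFs of the stretch described above and genes of the prophage list, and lowered a nitric-oxide reductase subunit and genes for flagella and ribosomes. An MT-A70 family protein (orf02412) rose by 7.70 ± 0.66 and a putative terminase small subunit (orf02410), part of the enzyme that packs phage DNA, by 7.60 ± 0.68 on the log2 scale. Nitric-oxide reductase subunit C (orf00271) fell from 2078 ± 1523 to 64.1 ± 16.0 normalised RPKM (log2 fold change -5.02 ± 0.75, adjusted p = 1.5e-05). Glutaryl-CoA dehydrogenase (orf00978, -5.25 ± 0.53), a putative regulator (orf01832, -4.54), a deoxyribodipyrimidine photolyase (orf01831, -4.53), which repairs light damage to DNA, and a short-chain dehydrogenase (orf01833, -4.47) fell as well. All 10 named genes, the plasmid-like orf04259 and orf04245 and the partitioning protein orf04263 included, kept their call in all leave-one-out fits.

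The flagellum and chemotaxis list of R90 alone had a median of -0.999 (-1.88 as deposited, camera adjusted p = 1.1e-10, 0.394 estimated). Of its 90 genes, 2 rose and 43 fell (2 and 45 in the list, 0 and 69 as deposited, 0 and 43 quantile-normalized). Flagellin type B (orf03194, -3.29 ± 0.47) and a chemotaxis transducer (orf01610, -3.79 ± 0.32) fell. The ribosomal protein list had a median of -0.93 (-1.84 as deposited, camera adjusted p = 7.2e-07, 0.709 estimated). Of its 59 genes, 24 fell (0 and 57 as deposited). The falls included L33 (orf00732, -2.58). The wider list of 60 had the same calls and a median of -0.91 (camera adjusted p = 7.2e-07, 0.709 estimated). Iron uptake in R90 alone had a median of 1.14 (0.23 as deposited and 0.54 quantile-normalized, camera adjusted p = 6.7e-04, 0.394 estimated). Of its 31 genes, 16 rose and 1 fell (12 and 6 as deposited). A permease for siderophores loaded with iron (orf02457, 5.27 ± 0.55) rose. Prophage and mobile elements had a median of 0.90 (-0.01 as deposited, camera adjusted p = 9.2e-06, 0.451 estimated). Of its 48 genes, 22 rose and 3 fell (14 and 6 as deposited). A phage related DNA methyltransferase (orf02428, 5.72 ± 0.58) and terminase GpA (orf02439, 5.62 ± 0.41) rose. Amino acid biosynthesis by enzyme name had a median of -0.40 (-1.33 as deposited, camera adjusted p = 0.0167, 0.709 estimated). Of its 71 genes, 1 rose and 10 fell (1 and 49 as deposited). Denitrification had a median of -0.45 (-1.30 as deposited and -1.11 quantile-normalized, camera adjusted p = 0.261, not called). Among its 28 genes, 3 rose and 8 fell (3 and 15 as deposited). edgeR called 1333 genes, 773 higher and 560 lower at day 7, without overlap for 1305 of them and for 55.1% of all genes. The split was 323 higher and 1654 lower as deposited and 548 higher and 600 lower quantile-normalized. The median of all genes lay at -0.87 and -0.22 in these fits.

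In co-culture, R90 raised phage and iron uptake genes and lowered a protein of nitrite reductase heme synthesis between days 0 and 7. Phage terminase GpA (orf02439) went from 3.02 ± 1.07 to 354 ± 112 normalised RPKM (log2 fold change 6.74 ± 0.49, adjusted p = 6.9e-10), and the MT-A70 protein orf02412 rose by 9.07 ± 0.72. Isochorismatase (orf03981), an enzyme family of siderophore synthesis, went from 3 to 646 counts over the groups, a ratio of 217 (counting interval 73.9 to 1054). The nitrite reductase heme biosynthesis H protein (orf00575) went from 89 counts to 1, a ratio of 0.0113 (0.000283 to 0.0647). A sodium-dependent transporter (orf00629) went from 309 to 3, a ratio of 0.00978 (0.00201 to 0.0288), and malonate decarboxylase subunit delta (orf02680) from 50 to 1, a ratio of 0.0201 (0.000500 to 0.118). A peptidyl-prolyl isomerase (orf01717) and an ArsR family regulator (orf02673) had 0 counts at day 7 and were at least 2.98-fold and 2.65-fold lower, from a floor of 3 counts over the group. The isomerase lost its call without day 0 co-culture replicate 3 and day 7 co-culture replicates 2 and 3 and the regulator without day 0 co-culture replicate 1 and day 7 co-culture replicates 2 and 3. The other 8 of the 10 named genes kept theirs in all leave-one-out fits.

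In co-cultured R90 the prophage list had a median of 1.86 (0.84 as deposited, camera adjusted p = 1.1e-10, 0.394 estimated). Of its 48 genes, 33 rose (20 and 1 as deposited). A phage tail tube protein (orf04198, 7.91 ± 1.63) was among the rises. Iron uptake in co-cultured R90 had a median of 1.41 (0.31 as deposited, camera adjusted p = 4.7e-05, 0.394 estimated). Of its 31 genes, 17 rose and 1 fell (12 and 5 as deposited). The siderophore permease orf02457 rose by 6.30 ± 0.67 on the log2 scale. Pili, adhesion and tight adherence had a median of 0.99 (-0.05 as deposited, camera adjusted p = 0.0150, 0.709 estimated). Of its 28 genes, 13 rose and 1 fell (5 and 5 as deposited). The flagellum and chemotaxis list had a median of -0.94 (-1.97 as deposited, camera adjusted p = 6.4e-06, 0.451 estimated). Of its 90 genes, 2 rose and 43 fell (0 and 63 as deposited). The ribosomal protein list had a median of -0.42 (-1.43 as deposited, camera adjusted p = 0.0429, 0.927 estimated). Of its 59 genes, 3 rose and 16 fell (0 and 42 as deposited, 1 and 21 quantile-normalized). The wider list of 60 had the same calls and a median of -0.42 (camera adjusted p = 0.0436, 0.927 estimated). Denitrification had a median of -1.08 (-2.12 as deposited, camera adjusted p = 0.0594, not called). Of its 28 genes, 2 rose and 13 fell (0 and 15 as deposited). NirQ (orf00583, -4.82 ± 0.76), NirJ (orf00586, -4.47 ± 0.80) and nitric-oxide reductase subunit C (orf00271, -4.27 ± 0.77) fell. edgeR called 1586 genes, 805 higher and 781 lower at day 7, without overlap for 1325 of them and for 44.3% of all genes. The split was 335 higher and 1824 lower as deposited and 650 higher and 969 lower with limma on log2(RPKM + 1). The median of all genes lay at -1.09 and -0.45 in these fits.

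The interaction of culture and day in R90 included tryptophan synthase beta (orf03965, interaction -3.75 ± 0.67 on the log2 scale, adjusted p = 0.0123). It stood at 486 ± 286 in co-culture against 26.6 ± 4.70 alone at day 0 and at 106 ± 91.5 against 53.7 ± 17.6 at day 7. The ABC transporter orf00011 (-3.73 ± 0.68) moved the same way, and flagellin type B (orf03194, 2.81 ± 0.63) the other way. edgeR called 120 genes, 51 positive and 69 negative, with non-overlapping differences for 105 of them and for 11.99% of all genes (chance share not computed). The split was 3 and 7 as deposited, 21 and 45 with limma on log2(RPKM + 1), and 43 and 119 with DESeq2 size factors. The median of all genes lay at -0.09, and at -0.23, -0.49 and -0.23 in these fits. The count was 54 without day 0 co-culture replicate 1, 78 without day 0 co-culture replicate 2, 44 without day 0 co-culture replicate 3, 46 without day 7 co-culture replicate 2, 12 without day 7 co-culture replicate 3, 26 without day 0 R90 alone replicate 1 and 36 without day 0 R90 alone replicate 2 and day 7 R90 alone replicate 3. The beta subunit lost it without day 7 co-culture replicate 3, orf00011 without day 7 co-culture replicate 3 and flagellin type B without day 0 co-culture replicate 1, day 7 co-culture replicate 3, day 0 R90 alone replicate 1 and day 7 R90 alone replicate 3.

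The lists in this paragraph were not called for co-culture against alone, with medians and adjusted camera p given for days 0, 4 and 7. Nor were the lists above in comparisons for which they are not given. Brackets give higher and lower counts and medians that moved with scaling. In R79, multidrug efflux and antimicrobials had medians of -0.01, 0.19 and -0.19 (day 0, median 0.17 as deposited, 0.04 quantile-normalized, 0.00 with DESeq2 size factors; day 7, called 2 and 0, 0 and 1 as deposited, 0 and 1 quantile-normalized, camera p 0.581 to 0.849), with 5 of 23 genes higher and 2 lower at day 4. Pili, adhesion and tight adherence had -0.14, 0.42 and -0.32 (day 0, median 0.06 as deposited, 0.05 quantile-normalized, camera p 0.396 to 0.938), with PilQ (orf00389, 1.52) higher at day 4. Amino acid biosynthesis by enzyme name had -0.09, 0.12 and 0.08 (day 0, median 0.14 as deposited; day 7, called 1 and 0, 0 and 1 as deposited, median -0.20 as deposited, camera p 0.498 to 0.792), with 6 of 59 genes higher and 2 lower at day 4. In R90, exopolysaccharide, cellulose and biofilm had medians of -0.26, -0.27 and -0.11 (day 4, called 1 and 0, 0 and 10 as deposited, median -1.30 as deposited; day 7, median 0.10 quantile-normalized, camera p 0.199 to 0.833). Phosphate starvation had -0.00, 0.19 and -0.31 (day 0, median 0.03 as deposited, 0.18 quantile-normalized, 0.04 with DESeq2 size factors; day 4, called 0 and 0, 0 and 4 as deposited, median -0.95 as deposited, camera p 0.515 to 0.922). Cobalamin and B vitamins had 0.10, 0.27 and 0.16 (day 4, called 1 and 0, 0 and 3 as deposited, median -0.68 as deposited, camera p 0.257 to 0.548). Oxidative stress had -0.03, -0.42 and 0.23 (day 0, median 0.01 as deposited, 0.03 quantile-normalized, 0.02 with DESeq2 size factors; day 4, called 1 and 0, 0 and 8 as deposited, median -1.33 as deposited, -0.14 quantile-normalized, camera p 0.381 to 0.895), with superoxide dismutase (orf03790, 1.96 ± 0.33) higher at day 4. Nitrogen assimilation had -0.07, -0.75 and -0.50 (day 4, called 2 and 5, 0 and 10 as deposited, 2 and 0 quantile-normalized, median -1.75 as deposited, -0.24 quantile-normalized, camera p 0.680 to 0.785). The 71 R90 genes of amino acid biosynthesis by enzyme name had 0.06, 0.19 and 0.08 (day 4, called 7 and 7, 1 and 24 as deposited, median -0.73 as deposited; day 7, called 3 and 2, 1 and 1 as deposited, median -0.01 with DESeq2 size factors, camera p 0.0525 to 0.465). Flagellum and chemotaxis in R90 had -0.09 and -0.05 at days 0 and 4 (-1.13 as deposited at day 4, camera p 0.515 and 0.918), with 5 of 90 genes higher and 7 lower at day 4 (0 and 44 as deposited). Lists of under 5 members were not tested as lists. Of the storage list, the phasin orf02608 of R79 rose between days 0 and 7, by 2.42 ± 0.53 alone and 2.32 ± 0.54 in co-culture, and glycogen synthase of R90 (orf01751) fell, by -2.04 ± 0.34 and -2.51 ± 0.38. Of the R90 secretion list, its 1 member, an ImpA domain-containing protein (orf00760), rose between days 0 and 7, by 1.46 ± 0.29 alone and 2.18 ± 0.38 in co-culture. Of the amino acid biosynthesis list as fixed, imidazole glycerol phosphate synthase subunit HisH (orf00784) fell in R90 alone (-1.29 ± 0.25). Across all lists and comparisons camera called 23 of 85 tests in R79 and 22 of 95 in R90, and with an estimated correlation 0 in each. Median, mean and test differed in sign in 14 and 16 tests, of which 1 was called, amino acid biosynthesis by enzyme name in co-cultured R79.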

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

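Every result in this part is an interaction, a difference between cultures that itself differed between days 7 and 0 by edgeR's test, and no test here was chosen after the result was seen. In R79, 155 genes differed in this way. Positive among the named ones were a putative membrane protein (orf01572, 3.16), a response regulator (orf02891, 3.04), the GNAT acetyltransferase (orf02231, 2.96), the PQQ-dependent dehydrogenase (orf00016, 2.85) and a ribonuclease HII family protein (orf02385, 2.80), as log2 values. Negative were type II secretion system protein C (orf02045, -3.50), the lipid A deacetylase (orf02479, -3.22), a MutT/nudix protein (orf00459, -3.13), an RsmD family methyltransferase (orf01327, -2.98) and a helix-turn-helix protein (orf03198, -2.06). Of these 10, 7 kept their call in all 12 leave-one-out fits. The calls lost, all of the last 3 named, were 3 without day 7 R79 alone replicate 3 and day 0 co-culture replicates 1 and 2, 2 without day 7 R79 alone replicate 2, day 0 co-culture replicate 3 and day 7 co-culture replicates 1 and 3 and 1 without day 0 R79 alone replicates 1 and 2 and day 7 co-culture replicate 2. The count was 94 without day 0 co-culture replicate 1, 100 without day 0 co-culture replicate 3, 73 without day 7 co-culture replicate 2, 246 without day 0 R79 alone replicate 3, 91 without day 7 R79 alone replicate 2 and 98 without day 7 R79 alone replicate 3. Of 100 splits of the 12 libraries, the real one gave most calls with only these groups fitted, 173 against at most 125. Splits also undo a culture effect of 1 day, so chance stays open.

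In R90, 120 genes differed. Positive were a phage integrase (orf02628, 3.52), nitrate-inducible formate dehydrogenase beta (orf01773, 3.07), flagellin type B (orf03194, 2.81), paraquat-inducible protein A (orf04097, 2.77) and a putative lipoprotein (orf00407, 2.34). Negative were general secretion pathway protein I (orf03442, -5.31), sulfur transfer protein SirA (orf03206, -3.91), a rhodanese domain protein (orf01270, -3.76), tryptophan synthase beta (orf03965, -3.75) and an ABC transporter (orf00011, -3.73). The first 3 of these rest on 2, 1 and 2 counts over the co-culture group of day 7, so their fitted values are no bounds. None of the 10 kept its call in all 12 fits, with calls lost of 10 without day 7 co-culture replicate 3, 6 without day 7 R90 alone replicate 3 and day 0 co-culture replicate 1, 5 without day 0 R90 alone replicate 1 and day 7 co-culture replicate 2, 4 without day 0 co-culture replicate 3, 3 without day 0 R90 alone replicate 2, 2 without day 0 R90 alone replicate 3, day 7 R90 alone replicate 1 and day 0 co-culture replicate 2 and 1 without day 7 R90 alone replicate 2 and day 7 co-culture replicate 1. The count with 1 library left out ran from 12 to 161. Of 100 such splits, 1 (the real one) gave as many calls, 280 against at most 262, and chance stays open for the same reason. No biological explanation of these interactions was tested, nor were R79 reads for orf03965.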

How the results depend on the processing

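The count filter of edgeR, the fits without the top ORFs and the fit without the shallow library were tests chosen after the result was seen. All counts below are called genes, given as the value of the fit in the report and then of the alternative, with the cause not tested unless stated. For R79 at day 0 the 8 calls became 3 as deposited, 2 with quantile normalization, 30 with DESeq2, 4 with the count filter of edgeR and, with limma, 0 on log2(RPKM + 1) (240 at an unadjusted p under 0.05), 1 with 0.1 added, 0 with 10 added (233) and 0 with a robust prior (238). With only the groups of the comparison edgeR called 0 (262), where 4 residual degrees of freedom remain. R79 at day 7 went from 153 to 73 with quantile normalization and 236 with only its groups, and the R79 interaction from 155 to 83 with quantile normalization. R90 at day 0 went from 5 to 3 with quantile normalization, limma on log2(RPKM + 1), robust limma and a robust dispersion each, 2 with 10 added, 13 with DESeq2 and 38 with only its groups. R90 at day 4 went from 864 to 1804 as deposited, 292 with limma on log2(RPKM + 1), 262 with 0.1 added, 417 with 10 added, 297 with robust limma and 553 with only its groups. R90 at day 7 went from 390 to 163 as deposited and 216 with limma on log2(RPKM + 0.1). R90 alone between days 0 and 7 went from 1333 to 824 with limma on log2(RPKM + 1), 747 with 0.1 added and 813 with robust limma. The R90 interaction went from 120 to 10 as deposited, 66 with limma on log2(RPKM + 1), 43 with 0.1 added, 65 with robust limma, 280 with DESeq2 and 280 with only its groups. List tests called went from 23 in R79 and 22 in R90 to 0 in each with an estimated correlation, since that test allows for genes moving together.

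With single libraries left out, the counts ran for R79 from 0 to 79 (day 0), 572 to 903 (day 4), 56 to 126 (day 7), 708 to 873 (alone), 888 to 965 (co-culture over time) and 73 to 246 (interaction). For R90 they ran from 2 to 5, 586 to 952, 107 to 484, 1146 to 1318, 1239 to 1590 and 12 to 161. Samples of different groups share only a number. Same-number pairs all correlated best in R79 over time (0.01 to 0.13), not elsewhere, so pairing is open. With the number as a replicate block the counts were 9, 768, 171, 831, 1027 and 186 for R79 and 4, 828, 373, 1333, 1570 and 124 for R90, in the same order, with 25 and 23 lists called.

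Of 572 named values, 471 kept direction and call as deposited, 467 with quantile normalization and 459 with limma on log2(RPKM + 1), and of 568 tested by DESeq2, 563 did. With a library left out 3054 of 3552 did and none reversed. Of called list members between days 0 and 7, 58 of 63 in R79 alone, 57 of 64 in co-cultured R79, 58 of 69 in R90 alone and 54 of 69 in co-cultured R90 kept their call in all these fits. Reversals, all in R90, were orf00843 at day 7 (quantile normalization, 0.14), orf00215 at day 7 (limma on log2(RPKM + 1) and robust limma -0.92, 0.1 added -2.01) and, in co-culture over time, orf00219 (0.1 added, -0.31), orf03334 (as deposited, -0.0879), orf00686 (0.1 added, -0.72) and orf03546 (limma on log2(RPKM + 1) and robust limma -0.20, 0.1 added -1.23). No list reversed in its test. In 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split and the highest other gave 0 and 0 calls for R79 at day 0 (10 of 10 splits as large, with 262 at an unadjusted p under 0.05 in the real one), 620 and 0 at day 4, 236 and 0 at day 7, 734 and 0 alone and 1063 and 0 in co-culture, and 38 and 12, 553 and 0, 448 and 8, 1387 and 0 and 1579 and 0 for R90, with 1 split as large (the real one) in each of these. Co-culture replicate 1 of day 7 holds 39421 R90 counts, which limits what can be seen of rare transcripts, and without it the R90 count of day 7 was 406.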

Other observations

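The product groups in this paragraph and all tests in this part were chosen after the result was seen, and the bounds for excluding DNA, reads of the other strain and scaling were made stricter after their values were known. Of 12 R79 genes with products of DNA recombination and repair, 6 were called lower in co-culture at day 4 and none higher (0 of 12 called at day 7, and 2 of 11 lower and 0 of 11 called in R90 at days 4 and 7), with a median of -0.995, and no group in this paragraph was tested as a group. RecA (orf01615, -3.08 ± 0.44), which pairs DNA strands, an impB/mucB family protein (orf02324, -2.94 ± 0.40), a DNA polymerase (orf03119, -2.83 ± 0.47) and RadA (orf01072, -1.55 ± 0.31) kept their call in all leave-one-out fits. LexA (orf01158, -0.07), the repressor of the damage response, was not called. Of 22 conjugal transfer products 7 were higher and 1 lower, among them TrbJ (orf00578, 2.77 ± 0.41), TrbB (orf00574, 1.93 ± 0.44) and TraF (orf00569, 1.78 ± 0.37). In R90 at day 7, 3 of 4 such products were lower, all of them integrating conjugative element proteins (orf03736, -1.96 ± 0.35, orf04146, -2.04 ± 0.33 and orf04222, -1.81 ± 0.45).

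The R90 stretch orf04174 to orf04288 may reflect a mobile element copied or transcribed more after day 0, which the design did not test. Reads from R79 were excluded as the source, since its 12 top ORFs rose by a median of 9.18 (8.31 to 10.70) on the log2 scale in R90 alone, where no R79 cells were. DNA left in the RNA stays open, since the rise at the 10% point of the stretch, 0.0584% of that of the 12 (at most 0.207%), may lie outside a shorter copied segment, with 98 of 115 ORFs called higher. A change in copy number stays open as well.

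Of the R79 ORFs, 23 of 54 ribosomal and 19 of 37 respiratory ones were called higher in co-culture at day 4, though neither list was called with an estimated correlation (adjusted p = 0.482 and 0.378), and R90 reads could have been counted to them. Such reads would raise the same ORFs at day 0, by a predicted median of 0.43 for 19 respiratory and 0.98 for 23 ribosomal ORFs. The values were -0.11 (bootstrap over ORFs, not libraries, -0.36 to -0.01) and 0.30 (0.02 to 0.36). Without a library factor the first was 0.08 (-0.17 to 0.19), so such reads stay open for both. Respiratory and ribosomal calls were 24 and 31 quantile-normalized and 18 and 21 with DESeq2 size factors. Without a library factor the median of the 42 rose from 1.42 to 1.53. All are relative values, so scaling stays open. Growth or contact with R90 as a cause was not tested.

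A run of 45 R90 ORFs with phage products (orf02410 to orf02454) was higher in co-culture at day 4 (median 2.08, 43 called). Limits set after the result was seen may add to both. Over time it rose by 4.93 alone and 5.05 in co-culture. At day 0, at a higher R79 share, the median was -0.14 (bootstrap over ORFs -0.43 to 0.01, or up to 0.05 without a library factor). R79 RNA may differ by day, so its reads stay open. A single library was excluded, as the lowest median with 1 left out was 1.67 (without co-culture replicate 1, 35 called). Scaling stays open, as the median without a library factor was 1.195 with 20 called. At day 7 the median was 0.03, with 2 called. An earlier rise in co-culture was not tested.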
